A study of Homo sapiens with 33 samples.

How the data were processed

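Total RNA from 33 HCT116 samples in 11 groups of 3 was sequenced. Per the labels' protocols, 1 µg of phenol-chloroform RNA per sample went into a ribosome-depleted library (KAPA RNA HyperPrep with RiboErase), a kit that keeps the strand of the RNA. Per the submitters' processing notes, the reads were aligned with STAR to hg38. The notes give no version, and do not name the counting tool, the annotation, the strand setting or any filter. The deposited table holds raw gene counts, whole numbers for 62750 Ensembl gene IDs, with no normalisation by the authors, and all its columns map to a sample.

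The 47 entries for the Y copies of the pseudoautosomal regions, with 3.3e-06 percent of the counts, were left out. Symbols came from a reference table and were found for 62625 entries. Positions, strands and gene types came from GENCODE v29 on GRCh38, which holds 58279 of the entries and 84.6% of the counts. TALAM1 is not in that release. The feature opposite a gene was defined as one of which at least 50 bp of exon lie opposite the exons of 1 protein-coding gene, with at least 90% of its opposite overlap from that gene. These pairs, and the reading of genes through them, were added after the values were seen. The comparisons, tests, gene lists, named-gene rule and all alternatives but 3 were fixed before the data were examined.

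Features were kept by edgeR's filterByExpr with the 11 groups, which left 15116 holding 97.5% of the counts. Library sizes were scaled by the trimmed mean of M values (TMM). All 33 libraries entered one fit with 1 coefficient per group and 22 residual degrees of freedom, and 16 comparisons (10 main, 6 secondary) were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at an adjusted p of 0.05. All adjusted p-values of single features in the text are from that test unless another tool is named, and CPM values are TMM-scaled. The common biological coefficient of variation was 0.251. A count of 0 over a group allows up to 3 counts. Intervals and bounds cover counting error only, since the reads carry no molecular identifiers. Total counts per library are low, and in null_48h against PABPC1_48h (the depleted empty vector against PABPC1) edgeR's test, tested on simulated data with 13707 features tested, found 21 of 100 features changed 2-fold and 79 of 100 changed 4-fold, with 9 false calls (8.26%). DESeq2 found 26 and 79, with 10 false calls (8.70%).

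The named-gene rule took from each main comparison the 10 largest rises and 10 largest falls, and from each secondary comparison 5 and 5, among features past the threshold with the 3 libraries of one group all above or all below the other 3, a mean of at least 5 CPM over the 6 libraries, and a symbol that is no clone name, pseudogene or small RNA. It also took the PABPC family and, from each list, up to 4 members with the largest change past the threshold. The text prints part of these. A similar rule was applied to features opposite a protein-coding gene as defined above, an addition made after the strand was seen. It took more features in each direction and did not filter by name or type. Of several features opposite a gene, only that with the highest mean CPM was used.

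The 30 gene lists were tested with limma's camera on voom values, with a preset correlation of 0.01 between genes and with an estimated one, adjusted over the lists of a comparison, and read both by the members' own names and through the features opposite them, where at least 3 members had one. Counts adjusted over the list alone use edgeR's p-values of the members. The depletion score is the mean log2(CPM + 1), centred per feature, of the features higher minus that of the features lower in the depleted empty vector than in undepleted cells. It was compared with exact two-sided permutation tests of 3 against 3 libraries, whose smallest p is 0.1. Features opposite exons (2313) and introns (1718) were compared by permutation with 100000 resamples. For comparisons that share controls, 20 sets of unchanged groups were simulated against the same controls.

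Alternatives were DESeq2's size factors, library totals and the mitochondrially encoded mRNAs for scaling, DESeq2's Wald test (with a local dispersion trend where the parametric one was not well captured), a fit of only the 2 groups compared, no low-count filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, an estimated correlation for the lists, other settings of the score, and each library left out in turn. Removing the GC trend of each library, leaving out undepleted replicates 1 and 3, and leaving out the undepleted and PABP1212 libraries were added after seeing the data. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.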

Results

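The series holds 33 RNA sequencing libraries from HCT116, an established line of colon cancer cells, in 11 groups of 3. In these polyclonal cells both PABPC1 and PABPC4 carried an auxin-inducible degron (mAID) tag, and a Sleeping Beauty transposon carried either an empty vector or an expression construct. PABPC1 and PABPC4 are cytoplasmic poly(A)-binding proteins, which hold mRNA tails through RNA recognition motifs (RRMs). Doxycycline at 1 µg/mL and indole-3-acetic acid (IAA) at 0.5 mM served to degrade the tagged proteins and to switch on the construct. Per the labels, cells were treated for 25 days where the construct restored growth and for 48 h where it did not. Time therefore follows growth, except for PABPC1, which was taken at both times. Among the 48 h groups PABPC1 restored growth and the others did not. There an effect of a construct cannot be told from one of slower growth. The groups of 25 days were untreated empty-vector cells (here undepleted), PABPC1, PABPC4, PABPC1 with the RRM4 of PABPC1L, PABPC1 with the RRM4 of the yeast protein Pab1, and PABPC1 with RRM1 and RRM2 duplicated (PABP1212). The groups of 48 h were the treated empty vector, PABPC1, PABPC1 with the RRM4 of PABPC5 or of PABPC4L, and PABPC1 without RRM4. The total count per library ran from 401850 (undepleted replicate 3) to 1707095 (PABP1212 replicate 3), with a median of 876905. The labels do not state whether the 3 replicates were separate cultures, so all p-values measure the spread between these libraries only.

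The deposited counts lie mostly on the strand opposite to each annotated gene, a reading chosen after the values were seen. TALAM1 (ENSG00000289740), the antisense transcript of the nuclear long noncoding RNA MALAT1, had a mean count of 114667 over the 33 libraries, against 857 for MALAT1 itself, a ratio of 134. Both genes were singled out after their values were seen. TALAM1 alone took 12.6% of all counts. The feature opposite GAPDH, the glycolytic enzyme, had a mean of 8441 counts against 415 under GAPDH. Pairs of a protein-coding gene and a feature opposite its exons were kept at a mean of at least 50 counts on the feature. No minimum was set for the gene. Density was the count per kb of overlap for the feature, and per kb of all exons for the gene. Both choices favour the feature. Of these 836 pairs, the feature was denser in 832, and the median gene held 1.05% of the density of its partner (interquartile range 0.525% to 2.36%). Changes are therefore given for a feature opposite a gene ("opposite MCM2") where there is one, which 1699 protein-coding genes have. Counts under a gene's own name are thin beside those of its opposite feature, but not few in sum. Protein-coding features opposite exons of another protein-coding gene held 24.15% of all counts, and those with no gene opposite 14.87%. Own-name counts may come from either strand and are uncertain as to their transcript, as are all overlapping and antisense genes here. Positions are those of GRCh38, and each change is on the log2 scale with its standard error (SE) and n = 3 against 3 libraries.

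Libraries of 2 groups stood apart from the rest. TALAM1 took 2.94% of the counts of undepleted replicate 1, 0.933% of replicate 3, and 3.94%, 2.80% and 4.32% of the PABP1212 libraries. It took 6.26% in undepleted replicate 2, 9.93% to 12.4% in the other libraries of 25 days, and 16.4% to 21.7% in those of 48 h. In the same 5 libraries, the median gene held 1.77% to 3.32% of the density of its opposite feature, taken as above (the own-strand share). It held 0.637% to 1.36% in the other 28. Replicates of the undepleted group correlated at r = 0.641 to 0.843 across features, which are not independent replicates, and those of the other groups at 0.858 to 0.959. Empty-vector replicate 2 also differed from its group, with a TALAM1 share of 16.5% against 19.6% and 20.4%, an own-strand share of 1.36% against 0.990% and 0.960% and a chi-square per degree of freedom of 3.24 and 3.62 against replicates 1 and 3, which gave 2.05 between them. In PABP1212 against PABPC1, the log2 change of a feature rose with its GC content (Spearman correlation 0.466 across features), and in PABPC1 against undepleted cells it fell (correlation -0.395).

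**Figure D1:**
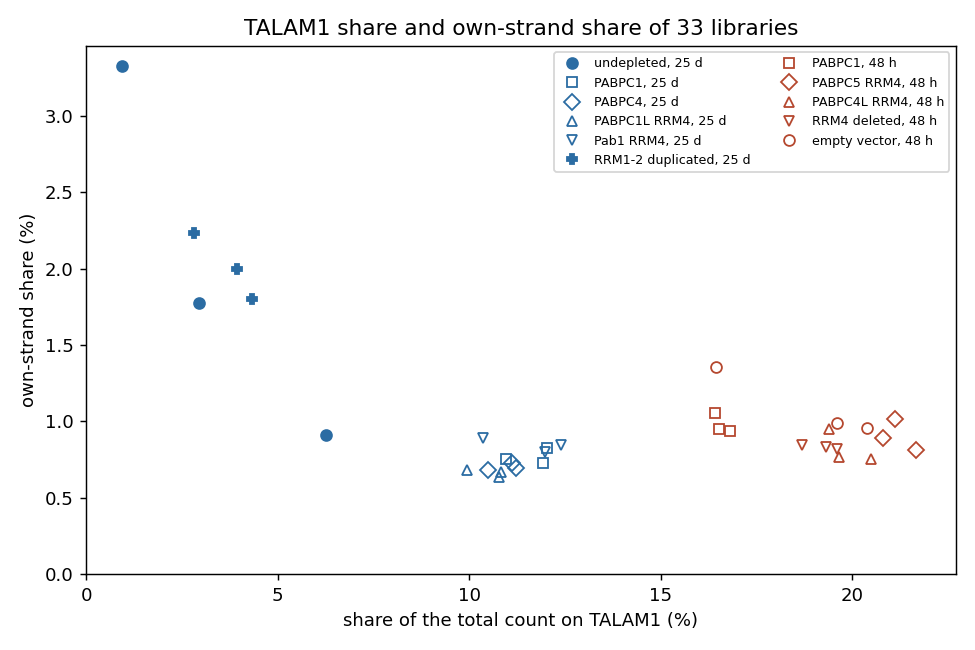
Share of the total count on TALAM1 (horizontal axis, %) against the own-strand share (vertical axis, %) for each of the 33 libraries, blue for 25 days and red for 48 h. Undepleted replicates 1 and 3 and the 3 PABP1212 libraries lie at 0.933% to 4.32% TALAM1 with an own-strand share of 1.77% to 3.32%.

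The targeted genes were read first. PABPC4-AS1 (chromosome 1, 39565067 to 39573203), of which 246 bp lie opposite PABPC4 exons, averaged 3010 ± 248 CPM (counts scaled to a common library size; SD, n = 3) in PABPC4 cells and 324 ± 19.4 in PABPC1 cells of 25 days. It lay between 169 and 455 CPM on average in the other 9 groups. Counts under PABPC4 itself averaged 125 ± 4.18 CPM in PABPC4 cells and 16.7 to 37.6 in the other 10 groups. PABPC1 (chromosome 8, 100685816 to 100722809) has no feature opposite it in the annotation, so only counts under its own name can be given. They averaged 222 ± 47.9 CPM in PABPC1 cells of 25 days, 61.6 ± 16.9 in PABPC4 cells, 118 ± 16.6 with the PABPC1L RRM4, 280 ± 21.4 with the Pab1 RRM4, 333 ± 21.6 in PABP1212 cells and 249 ± 89.4 in undepleted cells. At 48 h they averaged 184 ± 46.9 CPM with the empty vector, 140 ± 11.6 with PABPC1, 144 ± 21.8 with the PABPC5 RRM4, 155 ± 30.8 with the PABPC4L RRM4 and 134 ± 3.70 without RRM4. The degron removes protein, and the files do not say whether the mRNA of a construct is counted with the endogenous gene, so these levels check the PABPC4 construct only.

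**Figure D2:**
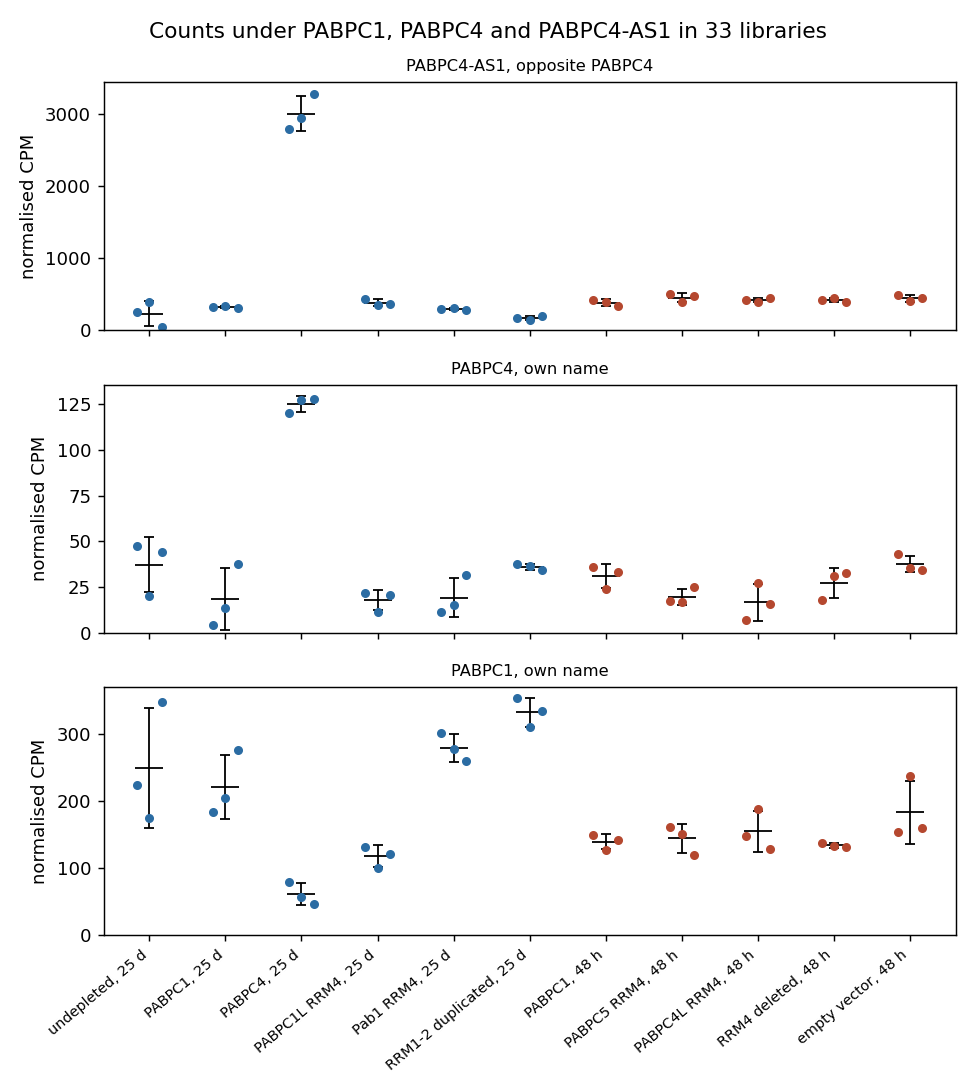
Normalised CPM under PABPC4-AS1, PABPC4 and PABPC1 in each library (points), with the group mean and SD (bars), blue for 25 days and red for 48 h. PABPC4-AS1 averaged 3010 CPM in PABPC4 cells and at most 455 in any other group.

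Empty-vector and PABPC1 cells, both treated for 48 h, ask what is lost when no PABPC1 or PABPC4 replaces the degraded proteins. Genes of DNA replication and of the unfolded protein response fell, between groups that by the labels differ in growth too. Opposite MCM2, a subunit of the replicative helicase (feature ENSG00000285600, chromosome 3, 127620106 to 127629049), counts averaged 29.8 ± 9.65 CPM in empty-vector cells and 230.3 ± 18.6 in PABPC1 cells, a change of -2.95 ± 0.32 (adjusted p = 1.1e-08). Opposite CLSPN, a replication checkpoint gene, the change was -2.49 ± 0.33 (adjusted p = 3.3e-07). It was -2.65 ± 0.42 opposite CHAF1A, a chromatin assembly factor (adjusted p = 9.7e-06), and -3.39 ± 0.41 opposite PRR11 (adjusted p = 3.0e-08; 97 bp of overlap). Of 5 DNA replication genes with an opposite feature 4 fell (4 adjusted over the list alone), with a median change of -2.65 (adjusted p = 0.000234 with an estimated correlation). The chaperone gene CALR fell from 1011 ± 23.0 to 232 ± 37.7 CPM on its opposite feature (chromosome 19, 12944118 to 12944487), a change of -2.12 ± 0.20 (adjusted p = 4.0e-11). Of 3 unfolded protein response genes read this way 2 fell (2 adjusted over the list alone; adjusted p = 0.019 with an estimated correlation). The glycolytic genes GAPDH and ALDOC fell on their opposite features, with changes of -1.69 ± 0.21 (adjusted p = 5.5e-08) and -2.74 ± 0.37 (adjusted p = 2.9e-07), but of 3 glycolysis and hypoxia genes read this way 2 fell and 1 rose (2 and 1 adjusted over the list alone), a list not past the threshold (adjusted p = 0.128 with an estimated correlation). Rises were smaller: opposite DUSP6, a phosphatase gene induced by growth signals, 0.90 ± 0.19 (adjusted p = 0.00124), opposite the angiogenic factor VEGFA 0.94 ± 0.23 (adjusted p = 0.00792), and opposite TRIM8 0.86 ± 0.19 (adjusted p = 0.00286). Of 6 immediate-early or AU-rich mRNAs read this way 1 rose (4 adjusted over the list alone), with a median of 0.49 (adjusted p = 0.00284 with an estimated correlation). Counts under the names of 34 replication-dependent histones and 73 cytosolic ribosomal proteins fell in 16 and 30 (21 and 44 adjusted over the list alone). The histone median was -1.92, or -1.71 with the members absent from a group at their bound (3 counts over the group), and the ribosomal median -1.08. Both calls were lost with an estimated correlation (adjusted p = 0.060 and 0.0677). The histone H2AC11 changed by -4.04 ± 0.54 (adjusted p = 3.5e-07), RPS3 by -2.32 ± 0.32 (adjusted p = 6.4e-07) and RPL11 by -2.87 ± 0.51 (adjusted p = 1.0e-04).

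In all, 802 of 15116 tested features changed between empty-vector and PABPC1 cells, 138 up and 664 down, of which 62 and 560 by at least 2-fold. Of the 1699 genes read through an opposite feature 19 rose and 172 fell. Scaling on the mitochondrially encoded mRNAs moved the median of all features from -0.01 to 0.43 and gave 154 rises and 145 falls, 193 of them among the 802. It ended 4 of the 13 calls named here (CHAF1A, VEGFA, TRIM8 and RPS3), and moved the median of ribosomal protein names to -0.63 and those of genes read opposite to 0.93 for immediate-early and AU-rich mRNAs, -0.42 for the unfolded protein response and -2.21 for DNA replication. This yardstick is 13 mRNAs read by own name, which themselves moved against the other features under the main scaling. Their median was -0.50 here, -0.45 for the deletion, -0.53 for the PABPC4L swap and 0.47 for the PABPC1L swap. With an estimated correlation the adjusted p was 0.561, 0.766, 0.608 and 0.550, though these lists passed with camera's preset one. For PABP1212 against PABPC1 the median was -0.63 and for PABPC1 against undepleted cells 0.54, also past the threshold with the preset correlation. A call ended by this scaling, here and below, depends on the yardstick and is not shown to be unchanged. The change itself can be as large as before. Under this scaling it was 1.38 opposite VEGFA and 1.32 opposite TRIM8, larger than under the main one. Opposite CHAF1A it was -2.21 and under RPS3 -1.87, smaller than under the main one. Leaving out 1 library at a time gave 450 (without empty-vector replicate 1) to 558 (without empty-vector replicate 2) calls, and VEGFA was lost without PABPC1 replicate 2 (adjusted p = 0.05002). Without the undepleted and PABP1212 libraries, an alternative chosen after seeing the data, the count was 1769.

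**Figure D3:**
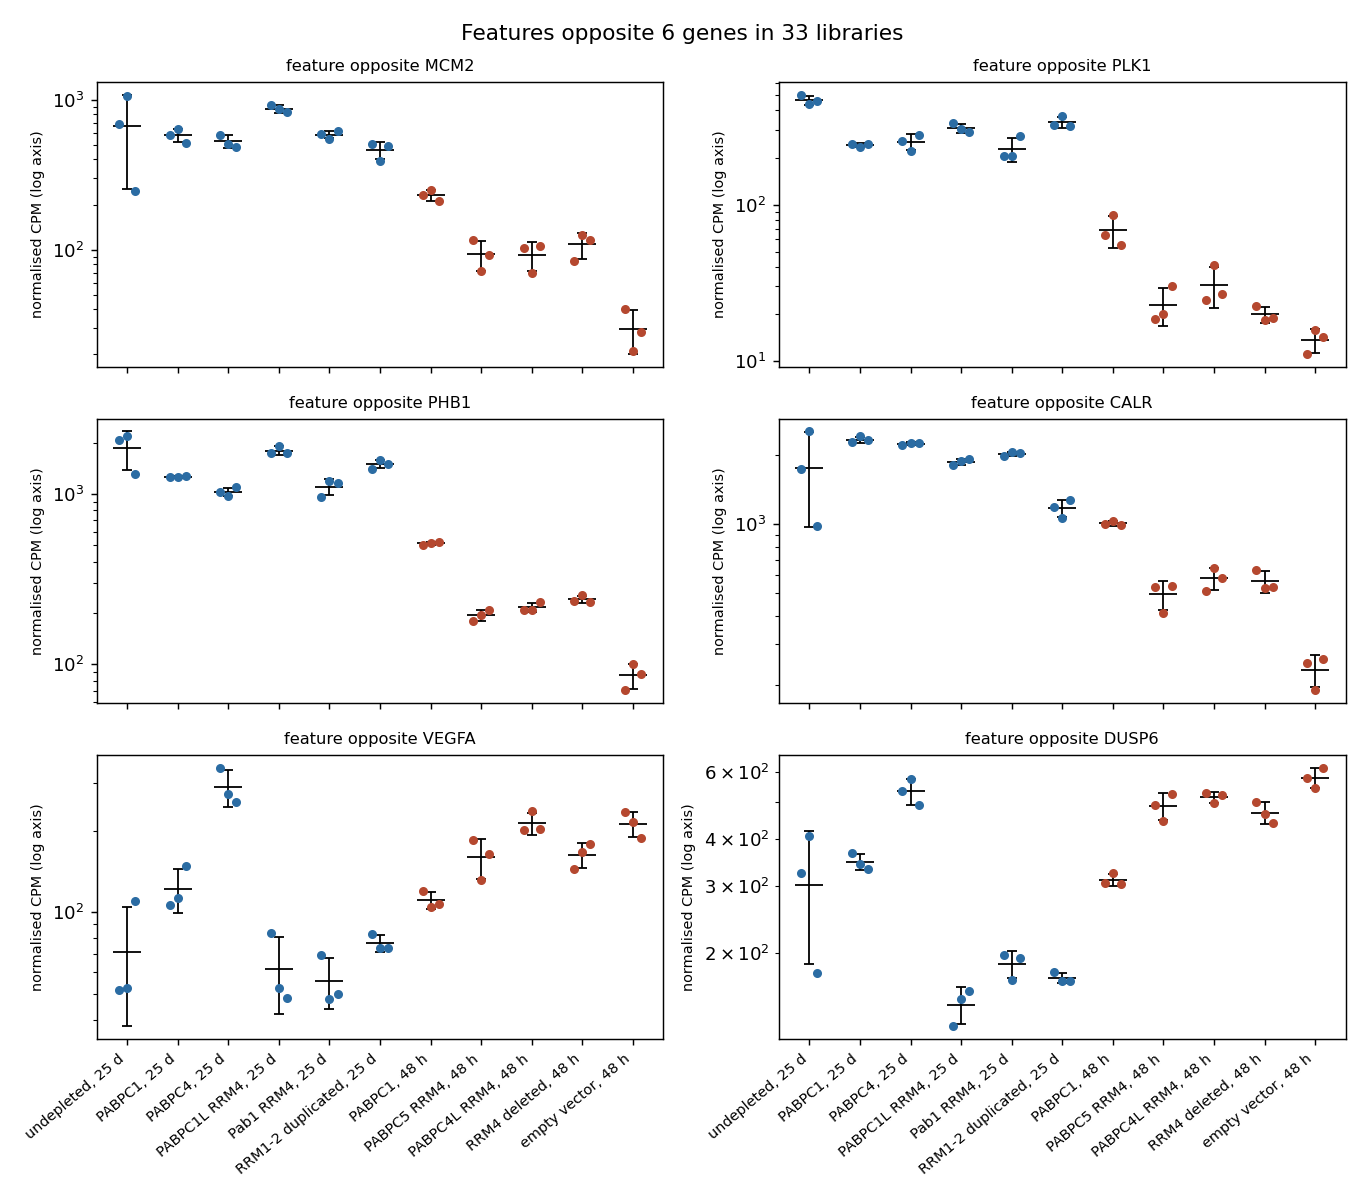
Normalised CPM (log axes) of the features opposite MCM2, PLK1, PHB1, CALR, VEGFA and DUSP6 in each library (points), with the group mean and SD (bars), blue for 25 days and red for 48 h. Opposite MCM2, CALR and PHB1 the 3 empty-vector libraries of 48 h lie below the 12 others of 48 h, with means of 29.8, 232 and 86.1 CPM.

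Deleting RRM4 from the replacement PABPC1, against intact PABPC1 at 48 h, asks what this domain is needed for. Opposite PLK1, the mitotic kinase (chromosome 16, 23687049 to 23687689), counts averaged 19.8 ± 2.40 CPM without RRM4 and 68.3 ± 15.7 with it, a change of -1.79 ± 0.27 (adjusted p = 5.7e-05). Opposite PHB1, a mitochondrial prohibitin (chromosome 17, 49404081 to 49405197), the change was -1.09 ± 0.18 (adjusted p = 0.00025). Opposite the nuclear lamina gene TMPO it was -1.21 ± 0.20 (adjusted p = 0.000316), opposite SAPCD2 -1.27 ± 0.22 (adjusted p = 0.000692) and opposite PRR11 -2.01 ± 0.35 (adjusted p = 0.00055). MCM2 and CALR changed the same way as in empty-vector cells, opposite MCM2 by -1.08 ± 0.28 (adjusted p = 0.0426) and opposite CALR by -0.84 ± 0.19 (adjusted p = 0.0179). Of the 5 DNA replication genes read this way 1 fell (4 adjusted over the list alone), with a median of -1.04 (adjusted p = 0.00656 with an estimated correlation). Of 6 immediate-early or AU-rich mRNAs 0 passed over all features (3 rose adjusted over the list alone), with a median of 0.50 (adjusted p = 0.00647 with an estimated correlation). Under their own names 8 of 73 ribosomal proteins and 5 of 34 histones fell (36 and 10 adjusted over the list alone), calls that were lost as lists (adjusted p = 0.158 for both with an estimated correlation). Rises were under names whose strand leaves the transcript uncertain. EIF2S1, which lies opposite ATP6V1D, rose by 1.19 ± 0.22 (adjusted p = 0.00108), CDK13 by 1.25 ± 0.23 (adjusted p = 0.00108), and C10orf55, opposite the protease gene PLAU, by 1.22 ± 0.18 (adjusted p = 5.1e-05). In all 136 features changed, 28 up and 108 down (21 and 85 by at least 2-fold). Of the genes read through an opposite feature 22 passed, all of them falls. Scaling on mitochondrial mRNAs moved the median of all features to 0.21 and left 12 rises and 7 falls, 12 of them among the 136. It ended 9 of the 10 named calls, all but that of EIF2S1. The falls among the 9 became smaller, with -1.78 opposite PRR11, -1.55 opposite PLK1 and -1.04 opposite SAPCD2. Opposite TMPO, PHB1, MCM2 and CALR they were -0.97, -0.86, -0.85 and -0.61. The rises among the 9 became larger, with 1.47 under CDK13 and 1.45 under C10orf55. Leaving out 1 library at a time gave 37 (without RRM4-deleted replicate 3) to 46 (without PABPC1 replicate 1) calls, whichever of the 6 was left out, against 750 without the undepleted and PABP1212 libraries. The MCM2 call was lost without any of the 6 (adjusted p up to 0.243 without RRM4-deleted replicate 1) and with the replicate block (0.0549). That of CALR was lost in all but 1 case (up to 0.126 without RRM4-deleted replicate 2). In these fits the change opposite MCM2 was -1.21 to -0.93 with 1 library left out and -1.08 with the block. Opposite CALR it was -0.86 to -0.80.

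The RRM4 of PABPC5 or of PABPC4L in place of that of PABPC1, at 48 h, asks whether the RRM4 of a relative can stand in. With the PABPC5 RRM4, counts fell opposite PHB1 (-1.39 ± 0.18, adjusted p = 2.6e-06), TMPO (-1.34 ± 0.20, adjusted p = 4.8e-05), PLK1 (-1.57 ± 0.26, adjusted p = 0.000229) and the histone variant gene H2AZ1 (-1.29 ± 0.22, adjusted p = 0.000393). Opposite MCM2 and CALR the changes were -1.29 ± 0.28 (adjusted p = 0.0117) and -1.03 ± 0.19 (adjusted p = 0.00173). The only 3 rises were under BHLHE40-AS1 (0.97 ± 0.22, adjusted p = 0.0128), EIF2S1 (0.84 ± 0.21, adjusted p = 0.0441) and SLC27A1 (0.76 ± 0.19, adjusted p = 0.0375). With the PABPC4L RRM4, counts fell opposite PHB1 (-1.24 ± 0.18, adjusted p = 5.6e-05) and TMPO (-1.10 ± 0.20, adjusted p = 0.00106). They also fell opposite MCM2 (-1.32 ± 0.28, adjusted p = 0.00946) and PLK1 (-1.14 ± 0.24, adjusted p = 0.00754). Opposite VEGFA and DUSP6 they rose by 0.94 ± 0.23 (adjusted p = 0.0322) and 0.72 ± 0.19 (adjusted p = 0.0447), and under RAD21 and ARFRP1 by 1.32 ± 0.24 (adjusted p = 0.00114) and 1.48 ± 0.25 (adjusted p = 0.000334). Of the 5 DNA replication genes read opposite 1 fell in each swap (3 adjusted over the list alone), with medians of -1.03 and -1.09 (adjusted p = 0.0139 and 0.0124 with an estimated correlation). Ribosomal protein names fell in 7 and 15 of 73 (26 and 39 adjusted over the list alone), lists not past the threshold with an estimated correlation (adjusted p = 0.110 and 0.0962).

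The PABPC5 swap changed 99 features (3 up, 96 down; 79 of the falls by at least 2-fold) and the PABPC4L swap 124 (24 up, 100 down; 13 and 79 by at least 2-fold). Of genes read through an opposite feature, 26 passed in the first, all of them falls, and 21 fell and 3 rose in the second. Scaling on mitochondrial mRNAs moved the median of all features to 0.19 and 0.22 and left 7 falls (3 of them among the 99) and 8 rises and 6 falls (6 among the 124). It ended every named call of both swaps, while the falls given became smaller and the rises larger. Opposite PHB1 the changes were then -1.19 and -0.99 (adjusted p = 0.288 and 0.289). The rise under BHLHE40-AS1 was 1.18 in the first swap (adjusted p = 0.0657), and that under ARFRP1 1.72 in the second (adjusted p = 0.233). With 1 library left out there were 28 (without PABPC5-swap replicate 3) to 63 (without PABPC1 replicate 1) and 33 (without PABPC4L-swap replicate 3) to 67 (without PABPC1 replicate 2) calls, and leaving out the undepleted and PABP1212 libraries 526 and 738. In the PABPC5 swap the rises under EIF2S1 and SLC27A1 were kept in 0 of these 6 fits (adjusted p up to 0.299 without PABPC1 replicate 3 and 0.293 without PABPC1 replicate 1), and both were lost with no low-count filter (0.0802 and 0.230). BHLHE40-AS1 was kept in 1 of 6 (up to 0.120 without replicate 3 of the swap), and MCM2 in 3 and CALR in 5 (up to 0.144 and 0.0604 without its replicate 2). In the PABPC4L swap the rises opposite VEGFA and DUSP6 were kept in 0 of 6 (up to 0.161 without replicate 2 of the swap and 0.194 without PABPC1 replicate 3), and both were lost with no low-count filter (0.0534 and 0.148). PLK1 was kept in 3 of 6 (up to 0.121 without PABPC1 replicate 2) and MCM2 in 4 (up to 0.103 without replicate 2 of the swap). The replicate block also ended EIF2S1 in the first swap (adjusted p = 0.0610) and DUSP6 in the second (adjusted p = 0.0612), and the filter of 1 CPM SLC27A1 (0.148) and DUSP6 (0.123).

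Against the empty vector, the same 3 constructs show what a PABPC1 without its own RRM4 still changes. Counts opposite MCM2 were higher with RRM4 deleted (1.86 ± 0.33, adjusted p = 0.00215), with the PABPC5 RRM4 (1.65 ± 0.33, adjusted p = 0.0124) and with the PABPC4L RRM4 (1.62 ± 0.33, adjusted p = 0.00658), as were counts opposite CALR, by 1.28 ± 0.20 (adjusted p = 0.000289), 1.09 ± 0.20 (adjusted p = 0.00346) and 1.32 ± 0.20 (adjusted p = 0.000122). GAPDH and CLSPN rose on their opposite features with RRM4 deleted (1.04 ± 0.20 and 1.81 ± 0.36, adjusted p = 0.00455 for both), PHB1 with the PABPC5 RRM4 (1.18 ± 0.19, adjusted p = 0.000616) and the folate enzyme gene MTHFD1 with the PABPC4L RRM4 (2.01 ± 0.37, adjusted p = 0.00186). The DNA replication genes read opposite rose in 2, 1 and 2 of 5 (3, 4 and 3 adjusted over the list alone), with medians of 1.81, 1.62 and 1.52 (adjusted p = 0.00489, 0.00143 and 0.00487 with an estimated correlation). Without RRM4 57 features changed (55 up, 2 down), with the PABPC5 RRM4 35, all up, and with the PABPC4L RRM4 77 (75 up, 2 down). With any 1 library left out there were 25 (without RRM4-deleted replicate 1) to 38 (without RRM4-deleted replicate 2), 4 (without empty-vector replicate 1) to 20 (without PABPC5-swap replicate 2) and 32 (without empty-vector replicate 1) to 48 (without PABPC4L-swap replicate 3) calls. Without empty-vector replicate 2 the calls of GAPDH and CLSPN in the deletion (adjusted p = 0.0690 and 0.110), of MCM2 and CALR in the PABPC5 swap (0.176 and 0.0993) and of MCM2 in the PABPC4L swap (0.113) were lost. MCM2 was kept in 3 of 6 such fits in the PABPC5 swap and in 4 of 6 in the PABPC4L swap. Scaling on mitochondrial mRNAs moved the median of all features to -0.18, -0.22 and -0.17 and left 2, 3 and 11 calls. It ended CALR in all 3 constructs (adjusted p = 0.183, 0.603 and 0.138), GAPDH and CLSPN in the deletion (0.151 and 0.404), and MCM2 and PHB1 in the PABPC5 swap (0.0589 and 0.734). Removing the GC trend ended GAPDH too (0.0620), and leaving out the undepleted and PABP1212 libraries gave 560, 526 and 735. The replicate block left 20 calls for the PABPC5 swap.

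Tested directly against the deletion of RRM4, neither swap differed in a feature: edgeR's test called 0 for the PABPC5 RRM4 and 0 for the PABPC4L RRM4, with 743 and 625 features at an unadjusted p under 0.05. DESeq2 called 11 and 1 (1239 and 1059 at an unadjusted p under 0.05), edgeR with only the 2 groups in the fit 46 and 24 (854 and 686), and edgeR without the undepleted and PABP1212 libraries 39 and 9. The 3 constructs moved in the same direction as the empty vector. Of the falls without RRM4, 88 of 108 were also falls with the empty vector, as were 87 of 96 with the PABPC5 RRM4 and 79 of 100 with the PABPC4L RRM4. Independent lists would share 4.74, 4.22 and 4.39, a value that leaves out the shared PABPC1 libraries, and unchanged groups simulated against those libraries shared a mean of 0, 0 and 0.05 falls, a value that leaves out the effects. In each pair 0 features changed in opposite directions. Over 7086 features with a mean of at least 20 CPM, the log2 changes of the deletion and the empty vector correlated at r = 0.69 across features, which are not independent replicates, with a covariance of 0.199. For the PABPC5 and PABPC4L swaps r was 0.71 and 0.65, with covariances of 0.184 and 0.181. The simulated groups gave a mean r of 0.49 in all 3 pairs and covariances of 0.0601, 0.0594 and 0.0598, so part of the excess may come from the shared controls. The differences of the covariances were 0.139, 0.125 and 0.121.

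The depletion score places each library between undepleted cells of 25 days and depleted empty-vector cells of 48 h, which differ in time as well as in depletion. It is the mean log2 CPM of 3614 features higher minus that of 3405 lower in empty-vector cells of 48 h than in undepleted cells, by at least 2-fold. PABPC1 cells of 48 h scored 0.778 ± 0.0636 (SD, n = 3), the RRM4 deletion 1.57 ± 0.0285, the PABPC4L RRM4 1.55 ± 0.0867, the PABPC5 RRM4 1.47 ± 0.0486 and the empty vector 2.04 ± 0.253. At 25 days PABPC1 scored -0.713 ± 0.0756, PABPC4 -0.562 ± 0.0397, the PABPC1L RRM4 -0.892 ± 0.0244, the Pab1 RRM4 -0.623 ± 0.0917, PABP1212 -1.99 ± 0.193 and undepleted cells -2.63 ± 0.825. In both of these groups the score rose with the TALAM1 share, from -3.43 at 0.933% to -1.79 at 6.26% in undepleted cells and from -2.20 at 2.80% to -1.82 at 4.32% in PABP1212 cells, so the place of PABP1212 near undepleted cells is not read as an effect of the construct. PABPC1 cells scored 1.49 higher at 48 h than at 25 days, more than the 1.26 between the empty vector and PABPC1 at 48 h. Only differences within a time are therefore read as differences between constructs. At 48 h these cannot be told from slower growth, since PABPC1 restored growth and the others did not. The deletion scored 0.796 above PABPC1 of 48 h, more than the spread between replicates, with the 3 libraries of each group apart in an exact two-sided permutation test (p = 0.1, the smallest that 3 against 3 allow; 0.114 adjusted over 16 comparisons). Chance keeps 3 and 3 libraries apart in 10% of splits. The exact test gave the same p in all 16 comparisons but the Pab1 RRM4 against PABPC1 (0.0903 higher, exact p = 0.2) and the PABPC4L RRM4 against the deletion (-0.0247, exact p = 0.9). The features were chosen on the empty-vector and undepleted groups, which are not independent of the score.

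**Figure D4:**
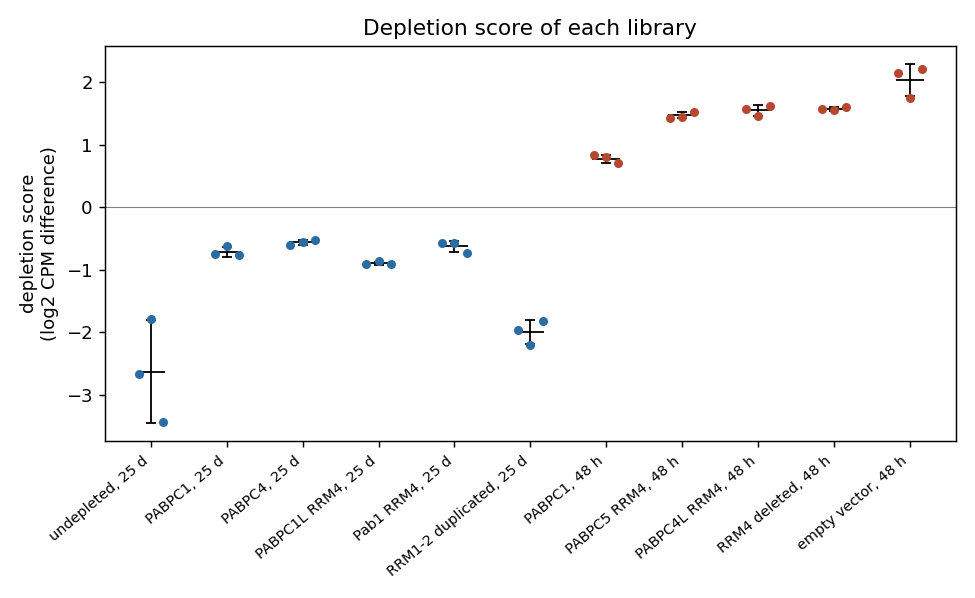
Depletion score (log2 CPM difference, vertical axis) of each of the 33 libraries (points) with the group mean and SD (bars), blue for 25 days and red for 48 h. The 3 RRM4 variants of 48 h average 1.47 to 1.57, between PABPC1 at 0.778 and the empty vector at 2.04.

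PABPC4 against PABPC1 as the only replacement, both at 25 days, asks whether the paralog does the same work. PABPC4-AS1 rose by 3.21 ± 0.31 (adjusted p = 2.7e-08) and counts under PABPC4 by 2.74 ± 0.40 (adjusted p = 1.5e-05), while those under PABPC1 fell by 1.86 ± 0.24 (adjusted p = 5.4e-07). The features opposite NRP1, a receptor of semaphorins and VEGF, and KRT7, a simple-epithelial keratin, rose by 3.50 ± 0.35 (adjusted p = 4.4e-10; 266 against 23.3 CPM) and 2.88 ± 0.36 (adjusted p = 2.4e-07). Opposite VEGFA and the kallikrein gene KLK10 the rises were 1.24 ± 0.23 (adjusted p = 0.00125) and 1.35 ± 0.26 (adjusted p = 0.00203), and under ARFRP1 3.12 ± 0.25 (adjusted p = 4.8e-13). Falls were fewer, among them counts under AKAP12, a scaffold of protein kinase A (-0.81 ± 0.16, adjusted p = 0.00383), and the feature opposite LRRC1 (-1.04 ± 0.23, adjusted p = 0.0104). In all 53 features changed, 41 up and 12 down (37 and 11 by at least 2-fold), and no fixed list passed limma's camera test (lowest adjusted p = 0.108, for the unfolded protein response by own name). Scaling on mitochondrial mRNAs left 6 rises and 3 falls (8 of them among the 53) and ended 6 of the 10 named calls. The changes of these 6 stayed close to those given. They were 2.79 under PABPC4, -1.81 under PABPC1, 1.39 opposite KLK10, 1.28 opposite VEGFA, -0.77 under AKAP12 and -1.01 opposite LRRC1. Leaving out the undepleted and PABP1212 libraries gave 230. With 1 of the 6 libraries left out there were 23 (without PABPC1 replicate 1) to 39 (without PABPC1 replicate 2) calls. AKAP12 was kept in 4 of 6 (adjusted p up to 0.0832 without PABPC1 replicate 3) and LRRC1 in 2 (up to 0.141 without PABPC1 replicate 1).

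The RRM4 of PABPC1L, an oocyte paralog, against that of PABPC1 at 25 days asks the same of a relative that restored growth. Of 3 glycolysis and hypoxia genes read opposite 2 fell (2 adjusted over the list alone; median -0.97, adjusted p = 0.0197 with an estimated correlation), against a median of -0.06 for 25 read by own name (adjusted p = 0.630 with an estimated correlation). Interferon-stimulated genes were lower than in PABPC1 cells. Of 12 under their own names 2 fell (5 adjusted over the list alone, median -0.49, adjusted p = 0.0494 with an estimated correlation), among them IFI6 (-3.38 ± 0.79, adjusted p = 0.0155). The 3 read opposite had a median of -2.04, past the threshold with the preset correlation. Opposite OAS1, with 92 bp of overlap, counts averaged 18.2 ± 8.03 CPM. They averaged 64.8 ± 4.93 in PABPC1 cells and 1.37 ± 1.62 in undepleted cells. Counts under the names of the hair keratins KRT32 and KRT36, whose transcript is uncertain, fell too (-4.77 ± 0.70, adjusted p = 1.9e-05, and -3.81 ± 0.67, adjusted p = 0.000362). On opposite features the class I gene HLA-F (-1.26 ± 0.22, adjusted p = 0.000278) and DUSP6 (-1.25 ± 0.20, adjusted p = 6.2e-05) fell. Histones under their own names rose in 2 of 34 (7 adjusted over the list alone; median 0.74, adjusted p = 0.0494 with an estimated correlation). The DNA replication genes read opposite had a median of 0.59, with 0 of 5 past over all features and 3 rises adjusted over the list alone (adjusted p = 0.00979 with an estimated correlation). Mitochondrial scaling lowered the histone median to 0.35 and this one to 0.19, and turned the median of DNA replication genes under their own names from 0.36 to -0.04. HIF1A-AS1, opposite the hypoxia factor gene HIF1A, rose by 1.51 ± 0.19 (adjusted p = 5.0e-07), SAPCD2 by 1.10 ± 0.19 (adjusted p = 0.000295) and the ubiquilin gene UBQLN1 by 0.99 ± 0.19 (adjusted p = 0.00106), both on opposite features. Counts under PABPC1 were lower by -0.91 ± 0.23 (adjusted p = 0.0258), a call kept in 1 of 6 fits with 1 library left out (up to 0.270 without PABPC1 replicate 3) and lost with the GC trend removed (0.0988) and under mitochondrial scaling (0.290). IFI6 was kept in 3 of 6 (up to 0.142 without PABPC1L-swap replicate 2). In all 142 features changed, 29 up and 113 down (23 and 91 by at least 2-fold). DESeq2's size factors gave 56 up and 115 down. Scaling on mitochondrial mRNAs moved the median of all features to -0.40, gave 5 up and 127 down (77 shared with the 142) and ended 5 of the 9 named calls. Any 1 library left out gave 71 (without PABPC1L-swap replicate 3) to 93 (without PABPC1 replicate 3), and leaving out the undepleted and PABP1212 libraries 783.

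With the RRM4 of yeast Pab1, some glycolytic and hypoxia genes were lower than with that of PABPC1 at 25 days. Opposite ALDOC counts averaged 67.3 ± 1.25 CPM with the yeast domain and 282 ± 27.0 with that of PABPC1 (-2.06 ± 0.28, adjusted p = 3.5e-06), and under SLC2A1, the glucose transporter, 70.4 and 252 (-1.84 ± 0.25, adjusted p = 3.5e-06). Opposite ALDOC undepleted cells averaged 40.5 ± 22.3 CPM, so there PABPC1 cells of 25 days are the group that stands high. Of 3 members read opposite 2 fell (3 adjusted over the list alone; median -1.14, adjusted p = 1.6e-05 with an estimated correlation). The 25 members read by own name had a median of -0.29, with 1 fall (1 adjusted over the list alone; adjusted p = 0.454 with an estimated correlation), so the fall is that of a few genes and not of the list. LDLRAD2, which lies opposite the perlecan gene HSPG2, fell by 1.53 ± 0.18 (adjusted p = 1.9e-07). On their opposite features VEGFA changed by -1.14 ± 0.24 and DUSP6 by -0.89 ± 0.19 (adjusted p = 0.0194 for both). Opposite DUSP6 undepleted cells averaged 302 ± 116 CPM, near the 347 ± 17.0 of PABPC1 cells. Interferon-stimulated genes under their own names rose as a list (0 of 12 past over all features, 3 adjusted over the list alone, median 0.57, adjusted p = 0.00355 with an estimated correlation). The 3 read opposite had a median of 1.05, past the threshold with the preset correlation. Opposite OAS1, with 92 bp of overlap, counts averaged 157 ± 16.1 CPM. They averaged 64.8 ± 4.93 in PABPC1 cells and 1.37 ± 1.62 in undepleted cells. The only 5 single rises were opposite SP110 (1.00 ± 0.21, adjusted p = 0.0194), under the apoptosis regulator CFLAR (1.66 ± 0.30, adjusted p = 0.00173) and under SWINGN (2.60 ± 0.57, adjusted p = 0.0225), CLEC5A and PTGFR. Folds are not given for CLEC5A, which lies opposite MGAM (17.5 CPM against 1.09, 3 counts in all in PABPC1 cells; adjusted p = 0.0194), and PTGFR (90.3 ± 64.7 CPM against a count of 0). In all 24 features changed, 5 up and 19 down (5 and 17 by at least 2-fold). Scaling on library totals gave 8 up and 15 down, and scaling on mitochondrial mRNAs 0 up and 3 down (3 of them among the 24), ending 9 of the 10 named calls. Leaving out 1 library gave 10 (without PABPC1 replicate 2) to 15 (without Pab1-swap replicate 3) calls, and leaving out the undepleted and PABP1212 libraries 160. DUSP6 and SWINGN were kept in 0 of these 6 fits (adjusted p up to 0.261 without Pab1-swap replicate 2 and 0.3995 without PABPC1 replicate 1), CLEC5A in 1 (0.276 without Pab1-swap replicate 1), VEGFA in 2 (0.261 without Pab1-swap replicate 2), SP110 in 2 (0.285 without Pab1-swap replicate 1) and CFLAR in 5 (0.0875 without PABPC1 replicate 2). DESeq2 did not call PTGFR (adjusted p = 0.842), library totals ended VEGFA (0.0539), no low-count filter DUSP6 (0.0761) and SP110 (0.0511), and the filter of 1 CPM DUSP6 (0.0835).

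PABP1212 against PABPC1 at 25 days rests on the 3 libraries with a TALAM1 share of 2.80% to 4.32% and an own-strand share of 1.80% to 2.23%, against at least 10.96% and at most 0.828% in the PABPC1 libraries. Counts under PABPC1 were higher by 0.59 ± 0.21 (adjusted p = 0.0267), with the own-strand share higher too. The call was kept in 2 of 6 fits with 1 library left out (adjusted p up to 0.159 without PABPC1 replicate 1) and lost with DESeq2 (adjusted p = 0.121) and with its size factors (adjusted p = 0.104). Opposite CHAF1A and TONSL, genes of chromatin assembly and of replication fork repair, counts rose by 1.67 ± 0.27 (adjusted p = 3.9e-06) and 1.52 ± 0.30 (adjusted p = 9.7e-05). USP34-DT, opposite the nuclear exporter XPO1, changed by -3.96 ± 0.61 (adjusted p = 3.3e-05), and the feature opposite ARHGAP5 by -4.20 ± 0.53 (adjusted p = 2.7e-06). Opposite ALDOC and GAPDH the changes were -2.79 ± 0.28 (adjusted p = 4.6e-10) and -1.10 ± 0.20 (adjusted p = 3.5e-05). Opposite ALDOC PABP1212 cells averaged 40.3 ± 17.7 CPM, near the 40.5 ± 22.3 of undepleted cells. The glycolysis and hypoxia genes read opposite fell in 3 of 3 (3 adjusted over the list alone; median -1.10, adjusted p = 0.0331 with an estimated correlation), the only 1 of 18 lists past the threshold kept with an estimated correlation. That median was -0.02 under mitochondrial scaling, and the same list by own name, with 25 members, had a median of 0.73 (adjusted p = 0.224 with an estimated correlation), so no fall of the list is claimed. In all 5771 features changed, 2661 up and 3110 down, and of genes read opposite 77 rose and 701 fell. DESeq2's size factors gave 2011 up and 3639 down, library totals 4157 and 2269 (median of all features 0.37), and mitochondrial scaling 6736 and 912 (median 1.15), with GAPDH no longer called (adjusted p = 0.952). With the GC trend of each library removed, 66.35% of the features were called again.

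Undepleted cells are the reference for both a full replacement and a full loss, with a TALAM1 share of 0.933% to 6.26% and an own-strand share of 0.910% to 3.32%. In PABPC1 cells of 25 days, BMP4, a growth factor gene, fell by 4.19 ± 0.58 (adjusted p = 3.6e-07) under its own name, and THAP11, which lies opposite CENPT, rose by 4.29 ± 0.29 (adjusted p = 1.1e-16). The feature opposite the interferon-induced gene OAS1, with 92 bp of overlap, rose by 5.24 ± 0.62 (adjusted p = 1.4e-08; 4 counts in all in undepleted cells) and that opposite C21orf91 by 4.11 ± 0.40 (adjusted p = 3.8e-11). Lists read by own name mostly fell (medians of -1.36 for DNA replication, -0.95 for the heat shock response and for NMD factors, -0.83 for the respiratory chain and -0.69 for ribosomal proteins). The own-strand share fell as well, from a mean of 2.00% in undepleted cells to 0.770%, so these medians are not read as changes of the genes. Cholesterol synthesis genes read opposite rose in 4 of 4 (4 adjusted over the list alone; median 0.99, adjusted p = 0.0237 with an estimated correlation), a direction that turned to -0.29 under mitochondrial scaling. The count of 4489 changed features (2383 up, 2106 down) is not stable: it was 19 with only the 2 groups in the fit, 824 (650 of them shared) without undepleted replicates 1 and 3, and 2868 (without undepleted replicate 1) to 6967 (without undepleted replicate 2) with 1 library left out. Library totals gave 1954 up and 2857 down, and mitochondrial scaling 920 up and 6130 down (median of all features -0.99).

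Empty-vector cells of 48 h against undepleted cells hold the widest contrast, in which time and treatment differ too. Opposite PLK1, TMPO, PHB1 and MCM2 counts changed by -5.08 ± 0.26 (adjusted p = 1.6e-22), -4.62 ± 0.22 (adjusted p = 1.3e-23), -4.43 ± 0.20 (adjusted p = 1.1e-24) and -4.49 ± 0.32 (adjusted p = 3.2e-15), and opposite CALR by -2.92 ± 0.21 (adjusted p = 2.6e-17). Opposite the transcription factor genes HIVEP2 and EGR3 they rose by 4.80 ± 0.31 (adjusted p = 1.0e-18) and 4.79 ± 0.45 (adjusted p = 4.3e-13). Under their own names 33 of 34 histones, 67 of 73 ribosomal proteins and 16 of 23 mitosis genes fell (33, 68 and 17 adjusted over the list alone; adjusted p = 0.0117 for each with an estimated correlation), while the own-strand share fell from a mean of 2.00% to 1.10%, so part of these falls may be leak. The medians were -4.48, -2.94 and -3.80, or -4.45 and -3.44 for histones and mitosis genes with absent members at their bound. Immediate-early and AU-rich mRNAs read opposite rose in 5 of 6 (5 adjusted over the list alone; median 1.74, adjusted p = 0.00402 with an estimated correlation). In all 7756 features changed, 3992 up and 3764 down, against 3458 with only the 2 groups in the fit and 5611 without undepleted replicates 1 and 3. Mitochondrial scaling moved the median of all features to -0.27.

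PABPC1 cells of 48 h against those of 25 days measure what differs between the reference groups of the 2 times. Immediate-early genes were higher at 48 h: IER2 on its opposite feature by 1.71 ± 0.18 (adjusted p = 1.7e-10), and under their own names FOSB by 2.93 ± 0.36 (adjusted p = 1.4e-08) and EGR1 by 2.76 ± 0.26 (adjusted p = 2.8e-11). Of 27 under their own names 17 rose (18 adjusted over the list alone; adjusted p = 0.0843 with an estimated correlation), as did 3 of the 6 read opposite (3 adjusted over the list alone; adjusted p = 0.00998 with an estimated correlation). DNA replication genes read opposite fell in 3 of 5 (5 adjusted over the list alone; median -0.90, or -0.52 under mitochondrial scaling; adjusted p = 0.00998 with an estimated correlation), with MCM2 at -1.33 ± 0.26 (adjusted p = 0.000294). CALR fell by 1.21 ± 0.19 on its opposite feature (adjusted p = 4.6e-06). The feature opposite OAS1 fell by 3.79 ± 0.53 (adjusted p = 3.8e-07). Counts under PABPC1 fell by 0.67 ± 0.22 (adjusted p = 0.0318), a call kept in 2 of 6 fits with 1 library left out (adjusted p up to 0.220 without PABPC1 replicate 3 of 25 days) and lost under 5 of 10 other settings (adjusted p up to 0.793 under mitochondrial scaling). In all 2507 features changed, 1310 up and 1197 down, against 1475 up and 233 down under mitochondrial scaling (median of all features 0.41). Features opposite exons and introns moved apart between the groups as well. The ratio of counts opposite introns to counts opposite exons was 0.123 ± 0.00175 in PABPC1 cells of 25 days, 0.179 ± 0.00299 at 48 h, 0.199 ± 0.00232 without RRM4 and 0.230 ± 0.00264 with the empty vector (exact permutation p = 0.1 for each of the last pair against PABPC1 at 48 h, n = 3).

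Over all 16 comparisons, 84 of 480 tests of the 30 fixed lists by own name passed with camera's preset correlation and 11 with an estimated correlation, and 53 of 240 tests by opposite gene passed, 31 of them with an estimated correlation.

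**Figure D5:**
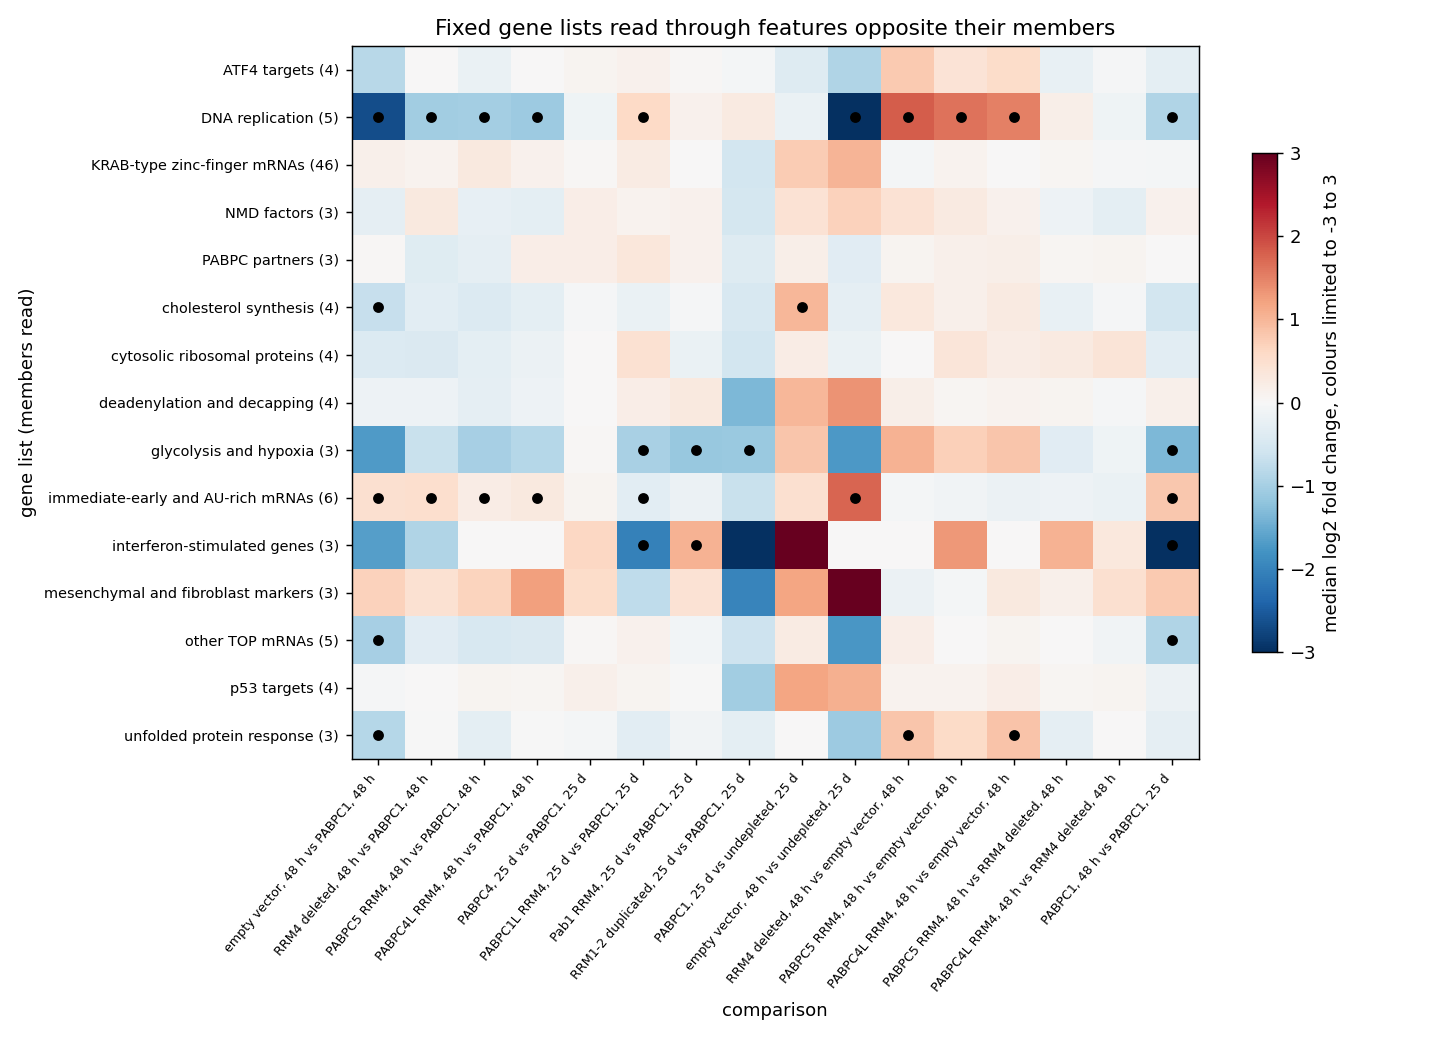
Median log2 fold change (colour, limited to -3 to 3) of each of 15 gene lists read through features opposite their members (vertical axis, number of members in brackets) in each of the 16 comparisons (horizontal axis). Dots mark adjusted p under 0.05 with an estimated correlation; DNA replication lies at -2.65 with the empty vector against PABPC1 at 48 h.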

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

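Removing the GC trend and leaving out the undepleted or PABP1212 libraries were chosen after seeing the data. The other alternatives were set beforehand. No named feature reversed under any alternative. The 106 named calls are pairs of a feature and a comparison, so a feature named in several comparisons, such as that opposite MCM2, counts in each. Of 1685 values of these calls under the alternatives, 1497 kept their direction and call. The other 188 kept the direction and lost the call, 60 of them under mitochondrial scaling. Counts of calls were less stable, and the cause was not tested except where said. At these totals and this spread between libraries, most simulated changes of 2-fold were missed. The simulation held depth and spread fixed, so it does not tell their parts. At the same depth, the empty vector against PABPC1 gave 802 calls in the shared fit and 1418 with only the 2 groups.

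DESeq2's size factors left all 17 results they apply to within 1.5 times. Library totals gave 213 calls without RRM4 against PABPC1, 179 with the PABPC5 RRM4 and 215 with the PABPC4L RRM4. Mitochondrial scaling gave 299 for the empty vector, 19, 7 and 14 for the deletion and the PABPC5 and PABPC4L swaps against PABPC1, 9 for PABPC4, 3 for the Pab1 RRM4, 7050 for PABPC1 against undepleted cells, 2, 3 and 11 for the deletion and both swaps against the empty vector, and 1 for the PABPC4L swap against the deletion.

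DESeq2's Wald test gave 1216 calls for the empty vector, 410, 264 and 363 for the deletion and the PABPC5 and PABPC4L swaps against PABPC1, 120 for PABPC4, 345 for the PABPC1L RRM4, 71 for the Pab1 RRM4, 198, 162 and 244 for the deletion and both swaps against the empty vector, and 11 and 1 for the swaps against the deletion. With only the 2 groups in the fit, which then rests on their own spread, the counts in the same order were 1418, then 843, 571 and 786, then 302, 1049 and 272, then 289, 269 and 454, then 46 and 24. They were 19 for PABPC1 and 3458 for the empty vector against undepleted cells. Leaving out the undepleted and PABP1212 libraries gave 1769, then 750, 526 and 738, then 230, 783 and 160, then 560, 526 and 735, then 39 and 9 in that order. The common spread of the fit with all groups includes these libraries. Without undepleted replicates 1 and 3, PABPC1 against undepleted cells gave 824.

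Removing the GC trend gave 237 for the PABPC1L RRM4, 44 for the Pab1 RRM4, 116, 65 and 152 for the deletion and both swaps against the empty vector and 1 for the PABPC4L swap against the deletion. That last comparison also gave 1 with no low-count filter and 1 with the filter of 1 CPM. With an estimated inter-gene correlation, 11 of the 84 list calls by own name passed. The depletion score of the deletion over PABPC1 lay between 0.593 and 1.00 under all alternatives.

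Of the counts the replicate block moved only that of the PABPC5 swap against the empty vector, to 20 calls. Among named calls against PABPC1 it ended MCM2 in the deletion (adjusted p = 0.0549), EIF2S1 in the PABPC5 swap (0.0610) and DUSP6 in the PABPC4L swap (0.0612). Replicate numbers do not pair the libraries: deviations from the group means correlated at -0.00614 for equal numbers and 0.00309 for others.

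With 1 library left out, the arm left with 2 shares the spread of all groups, and the lowest and highest counts were 450 and 558 for the empty vector, 37 and 46, 28 and 63, and 33 and 67 for the deletion and the PABPC5 and PABPC4L swaps against PABPC1. They were 23 and 39 for PABPC4, 71 and 93 for the PABPC1L RRM4, 10 and 15 for the Pab1 RRM4, 4087 and 5205 for PABP1212, 2868 and 6967 for PABPC1 and 6781 and 8641 for the empty vector against undepleted cells. They were 25 and 38, 4 and 20, and 32 and 48 for the deletion and both swaps against the empty vector, and 1741 and 1880 for PABPC1 at 48 h against 25 days. For the swaps against the deletion edgeR's test gave 0 with each library left out, as it did with all 6 (743 and 625 at an unadjusted p under 0.05). The list calls lay between 81 and 85 with 1 replicate number left out of every group, and the score difference between 0.746 and 0.822.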

Other observations

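The tests of the strand, of sequencing depth (for all 5 libraries and for the undepleted pair), and of nuclear RNA in undepleted replicates 1 and 3 alone were chosen after the result was seen. The others were set out before their result was seen.

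In every 48 h comparison with PABPC1, features opposite exons lay below features opposite introns. The difference of their median log2 changes was -0.33425 for the empty vector, -0.19578 for the RRM4 deletion, -0.151 for the PABPC5 RRM4 and -0.167 for the PABPC4L RRM4 (permutation p = 1e-05, the smallest that 100000 resamples can give, across features, which are not independent). At 25 days it was 0.00141 for PABPC4 (permutation p = 0.884), -0.0860 for the PABPC1L RRM4 (permutation p = 1e-05), -0.0438 for the Pab1 RRM4 (permutation p = 0.00273) and 0.133 for PABP1212 (permutation p = 0.00101) against PABPC1. For PABPC1 against undepleted cells it was -0.233 (permutation p = 1e-05), past that of the deletion. For PABPC1 at 48 h against 25 days it was -0.355 (permutation p = 1e-05), as large as with the empty vector although both groups carry PABPC1. Shifts of this size thus also arise between groups that both have PABPC1 by design. No protein level was measured, so a partial loss in PABPC1 cells of 48 h is not excluded. In the empty vector and the deletion a loss of mature mRNA relative to unspliced RNA is a candidate explanation, as it called for a difference below -0.1. Slower growth, a change of transcription and a change in the share of nuclear RNA stay open and were not tested.

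The counts lie on features opposite genes, denser than the gene in 99.52% of the pairs, which is the pattern itself. These pairs were kept for a mean of at least 50 counts on the feature, so that share is partly set by the choice. Antisense transcription counted on its own strand, a biological explanation, was taken to call for no more density opposite exons than opposite introns. Of 732 genes with both kinds, features opposite exons were denser than features opposite introns alone in 72.27% (95% interval 68.87% to 75.48%). These are different features, and antisense transcripts denser over exons would give the same. The comparison thus does not exclude antisense transcription. A candidate explanation is that reads were counted with the strand setting opposite to that of the kit. As this calls for, the counts per kb of 3153 features rose with the share of their length opposite exons (Spearman correlation 0.3245 across features). Antisense RNA at some of these genes stays open. If this is so, a table counted on the other strand would show most mRNAs that are barely read here.

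The low TALAM1 share of undepleted replicates 1 and 3 and the PABP1212 libraries is not explained for all 5 by low sequencing depth, since 3 of the 5, the PABP1212 libraries, lie above the median total count of the 18 libraries of 25 days. In undepleted replicates 1 and 3 it stays open: both lie below that median, and 1 of the 2, replicate 3, below the lowest of the other 16. Replicate 1 lies above 3 libraries with a TALAM1 share of at least 9.93%. Nor is it explained for all 5 by less nuclear RNA, since only 2 of the 5 have an intron-to-exon ratio below that of the other 13 libraries of 25 days (0.107). For undepleted replicates 1 and 3 a lower share of nuclear RNA may be the source: 2 of the 2 lie below the other 16. The lowest of these 16 is undepleted replicate 2, at 0.1066, against 0.1047 in replicate 1 and 0.0932 in replicate 3. In the other groups of 25 days the ratio was at least 0.118. It is thus low in the whole undepleted group and barely parts replicate 1 from replicate 2. A GC content trend between libraries is not the whole cause of the changes in these comparisons, since 66.35% of the features called for PABP1212 and 69.04% of those for PABPC1 against undepleted cells were called again with it removed. The duplication of RRM1 and RRM2, and a difference in how these libraries were made, stay open, and the labels give no batch.

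Each comparison was also run on all 10 splits of its 6 libraries into 3 and 3, with only those libraries in the fit. In each, 1 of the 10 splits, the real one, gave a count as large as the real one, and 10 splits are too few for a share under 0.1. The real counts were 1418 for the empty vector, 843 for the deletion, 571 for the PABPC5 RRM4 and 786 for the PABPC4L RRM4 against PABPC1, 302 for PABPC4, 1049 for the PABPC1L RRM4, 272 for the Pab1 RRM4, 6759 for PABP1212, 19 for PABPC1 and 3458 for the empty vector against undepleted cells, 289, 269 and 454 for the deletion and both swaps against the empty vector, 46 for the PABPC5 swap against the deletion, and 3585 for PABPC1 at 48 h against 25 days, and the highest of the other splits was 0 in these. For the PABPC4L swap against the deletion the real count was 24 and the highest other 1.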
